A study of Arabidopsis thaliana with 6 samples.

How the data were processed

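Total RNA of 14-day-old Arabidopsis seedlings (Col-0, long days, 22 °C) was sequenced by the authors on a NovaSeq 6000 with paired reads of 150 bases, from libraries made with the TruSeq RNA kit, which does not mark strand. There were 6 libraries, 2 each of WT, jmj28 and JMJ28np5-OE, and samples were grouped by the genotype in the labels. The genome build was TAIR10 per the submitters' processing notes. The aligner, the counting tool, the test and their versions are not given in the sources used here.

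The 3 deposited tables of all genes compare the genotypes in pairs and hold, per the file headers, a log2 fold change, a signed fold change, a p-value, an FDR and a Bonferroni p for each gene. The deposited level of each gene is the higher of the genotype means, and its values are in RPKM, as the authors' numbers show when multiplied by exon length, since the file headers do not name the unit. The log2 fold changes come from the authors' own fit. A shorter deposited list holds 533 genes with a p-value under 0.05 and at least 1.5-fold lower in jmj28, of which 189 have an FDR under 0.05. The authors' FDR and Bonferroni p count all 34262 listed genes, including 10720 without reads.

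No value per library is in these tables, so the fit on counts or on log2 values chosen before the data were examined could not be run. The result of each comparison is therefore the authors' deposited FDR under 0.05 over 23540 genes, and this replacement was chosen after the files were seen. Each RPKM mean of a genotype is the average over its 2 libraries, each a whole number of reads scaled by exon length and library total. The totals and the reads were solved from the means with a tolerance of 1e-07, which gave 1 solution for 98.4% of the highest and second-highest means and more than 1 for 0 of them. This step was tested on simulated data, where 7550 of 7550 solved means gave the true reads. Unless both lower genotypes had 0 reads, the lowest genotype mean of a gene is known only through the deposited fold change, and its spread is then not known. Library totals ran from 10632893 to 19693228 reads, at which 1 read per kilobase is 0.094 to 0.051 RPKM. Over genes above 5 RPKM the log2 ratio between the libraries of a genotype had an SD of 0.18 in WT, 0.18 in jmj28 and 0.27 in JMJ28np5-OE. With 2 libraries per genotype a p-value measures only the spread between these samples, which can be technical.

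Coordinates were taken from the deposited tables and checked against the TAIR10 reference annotation, where 32548 listed genes were found and 32520 had the same start and end. Of the tested genes, 25.7% overlap another gene model. CO and FT were left out of all counts and tests after their values were seen, because their entries equal those of other genes.

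Gene lists were fixed before the data were examined. There were 25 lists with loci and 2 set by a rule, of which the transposable element list could not be formed because the reference marks no such genes. The lists cover the JMJ28 family, FBH factors, flowering promoters and repressors, morning and evening clock, salicylic acid, jasmonate, abscisic acid and cold, heat shock, touch and early stress, photosynthesis, iron, phosphate, nitrate, sulfur, flavonoids, glucosinolates, auxin, cell cycle, senescence, silenced loci, root, floral and seed markers, and organelle genes. EVD and MU1 are not listed in the tables, and HSP21, NRT2.2, SAG12, ATA7, A9, CRU2 and CRU3 had no reads. Each of the 26 lists was tested in each comparison with cameraPR of limma 3.58.1 in R 4.3.3 on the signed z of the deposited p-value, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 26 lists. The planned test on values per library, its estimated correlation and fry need all libraries and could not be run, so no list call can be given with an estimated correlation. On simulated data 18 of 20 shifted lists and 1 of 200 unshifted lists passed. The simulated genes were independent of each other. These counts therefore say nothing about lists whose members move together, for which the p can be too small. Counts adjusted over the list alone use Benjamini-Hochberg on the deposited p-values of the members.

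Named genes followed a rule set before the data were examined. It takes JMJ28, the 12 largest changes per direction and comparison among calls with a mean log2(RPKM + 1) of at least 1 whose libraries do not overlap between genotypes, at most 2 per direction without a symbol, up to 4 members of each list with the smallest FDR, and CO, FT, SOC1 and FLC. RPKM took the place of CPM in that rule, and where the libraries of a genotype were not recovered its mean was used. NAS4 and SPL5, the genes overlapping a named gene, and the genes whose values equal those of CO or FT were named after their values were seen.

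The overlap of the comparisons against WT was set beside the count for independent lists and beside 100 simulated draws of unchanged genotypes against the same WT libraries. The draws used a Wald test with 1 spread per genotype, not the authors' test. Alternatives were the thresholds of p and fold, a minimum of 1 RPKM, FDR over the tested genes, Bonferroni, leaving out organelle genes or overlapping models, a 1.5-fold rule on both libraries, an inter-gene correlation of 0.05, ranks, ratios of RPKM means, and each recovered library left out of the called values of named genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.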

Results

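RNA sequencing of Arabidopsis thaliana Col-0 seedlings, grown for 14 days under long days at 22 °C, compared 3 genotypes with 2 libraries each. The genotypes were wild type (WT), the mutant jmj28, and a line named JMJ28np5-OE. JMJ28 belongs to the JmjC-domain histone demethylases of the KDM3 type, enzymes that act on methylated lysine 9 of histone H3. The label OE was read as overexpression because JMJ28 itself was raised in that line. What np5 stands for is not given in the sources used here. The comparisons ask which transcripts change when JMJ28 is reduced and when it is raised, with flowering time genes of particular interest from the known link of JMJ28 to the photoperiod pathway.

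The files used here hold genotype means in RPKM and the authors' own tests, with no value per library. The whole reads of both libraries behind most means could be recovered from the means themselves. The WT libraries held 19693228 and 14309520 reads, the jmj28 libraries 13549528 and 11791666, and the JMJ28np5-OE libraries 12380403 and 10632893. The deeper and the shallower library of each genotype are named by depth below, because the means carry no replicate number. Reads could be recovered for the genotype with the highest and the second-highest mean of a gene, and for the lowest only where both lower genotypes had 0 reads. Leaving out 1 recovered library moved 40 of 229 called values of named genes by more than 1.5-fold. For those printed below the text gives log2 ratios of RPKM means without that library, calculated here from the recovered libraries, mostly for the library whose absence brought the value closer to 0. Of 34262 listed genes, 23542 had reads and a test, and 2 of these, CO and FT, were left out of every count for the reason given with the flowering genes.

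JMJ28 (AT4G21430, listed as B160, chromosome 4, 11407804 to 11412279, TAIR10) was lowest in jmj28 and highest in JMJ28np5-OE. WT held 399 and 273 reads, which are 6.90 and 6.50 RPKM in the deeper and shallower library. The JMJ28np5-OE libraries held 8865 and 9579 reads, or 244 and 307 RPKM. The log2 fold change of JMJ28 against WT was -1.10 in jmj28 (FDR 3.07e-08) and 5.38 in JMJ28np5-OE (FDR listed as 0) in the authors' deposited tables. Reads of the gene were thus still present in the mutant, at a size of 2.15-fold below WT in the authors' deposited table. Where in the gene they lie was not examined, so whether they come from intact transcript is not known. None of the other 5 family members on the list (IBM1, JMJ24, JMJ26, JMJ27 and JMJ29) passed FDR 0.05 against WT. Adjusted over the list alone, 1 member was lower in jmj28 and 2 were higher in JMJ28np5-OE, the second being JMJ29, with a log2 fold change of 0.50 (FDR 0.0748) in the authors' deposited table.

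In jmj28 against WT, genes for iron uptake were higher, and genes for phosphate starvation, defence and rapid stress responses were lower. IRT1, the main iron transporter of the root epidermis, had a log2 fold change of 0.97 (FDR 0.00165), and FRO2, the root ferric reductase, had 1.01 (FDR 0.009) in the authors' deposited table. Among the lower genes, PR1, a marker of salicylic acid defence, had a log2 fold change of -5.50 (FDR listed as 0) and ZAT10, a zinc finger factor of early stress responses, had -1.78 (FDR 5.03e-06) in the authors' deposited table. Without the deeper WT library the log2 ratio of ZAT10 was -1.02. In all, 49 genes were higher and 258 lower at FDR under 0.05 in the authors' deposited table, and 10 and 104 of them changed at least 2-fold.

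The iron deficiency list stood out among the higher genes. All 14 tested members lay above WT, 6 were called, 10 were called when adjusted over the list alone, and the set test gave an adjusted p of 1.97e-19 with limma's cameraPR. Besides IRT1 and FRO2 the called members were BHLH38 and BHLH100, transcription factors of the iron response, at 1.14 (FDR 0.00592) and 1.21 (FDR 0.00302), and the signalling peptide genes IMA1 and IMA3, at 0.83 (FDR 0.0134) and 0.65 (FDR 0.00228) on the log2 scale of the authors' deposited table. The jmj28 libraries did not move alike within this group. BHLH100 was at 24.8 RPKM in the deeper and 10.6 in the shallower library, whereas IRT1 was at 24.3 and 41.0 RPKM. Without the deeper jmj28 library the log2 ratio of BHLH100 was 0.47. CYP82C4, a cytochrome P450 of the iron response outside the list, had a log2 fold change of 0.96 (FDR 0.0072) in the authors' deposited table.

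Root markers rose as well, with 1 call among 14 tested members, 3 when adjusted over the list alone, and an adjusted p of 1.95e-05 with cameraPR. The called member was TIP2;3, a tonoplast aquaporin, at 1.01 (FDR 0.000131) in the authors' deposited table. AGP30, a root arabinogalactan protein gene, stood at 10.1 and 12.5 RPKM in the jmj28 libraries against 6.39 and 4.92 RPKM in WT. IRT1, FRO2 and other genes of the iron list are also expressed in roots, and the root markers moved in the same direction as the iron list. The root list was fixed as a marker of other tissue that the harvest could hold. Whether the jmj28 samples held a larger share of root was not tested, and it cannot be told apart here from a change of the iron genes. Cell cycle and DNA replication genes were higher by small amounts. All 17 lay above WT with a median log2 fold change of 0.26, 1 was called (2 adjusted over the list alone), and the set test gave an adjusted p of 1.32e-07. The called member was the mitotic cyclin gene CYCB1;2, at 0.53 (FDR 0.025) in the authors' deposited table. Of the 15 flavonoid genes, F3H alone was called, at 0.65 (FDR 9.86e-08) in the authors' deposited table, and the list did not pass the set test (adjusted p = 0.0788 with limma).

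Among the lower groups, all 11 phosphate starvation genes lay below WT (adjusted p = 7.27e-16, cameraPR). Of these 3 were called, and 10 when adjusted over the list alone. MGD3, a galactolipid synthase gene, had a log2 fold change of -1.74 (FDR 1.49e-08), SPX3 -1.56 (FDR 0.0259) and SRG3 -0.91 (FDR 0.00226) in the authors' deposited table. The nitrate list had 1 call of 5 and 2 adjusted over the list alone. That call was the nitrate reductase gene NIA2 at -0.31 (FDR 0.0182) in the authors' deposited table. The list's adjusted p of 0.0342 became 0.0641 with an inter-gene correlation of 0.05 and 0.138 on ranks. NRT2.5, a nitrate transporter gene outside the list, was at 2.0 and 3.4 RPKM in WT and had a log2 fold change of -3.40 (FDR 3.72e-08) in the authors' deposited table.

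The rapid touch, handling and early stress list had the lowest set-test p in jmj28. Of 18 tested members 17 lay below WT, 6 were called, 13 were called when adjusted over the list alone, and the adjusted p was 1.29e-23 with cameraPR. CAF1A, a deadenylase gene induced within minutes of stress, had a log2 fold change of -2.03 (FDR 8.3e-06), ERF104 -1.63 (FDR 0.000284) and the calmodulin-like gene TCH3 -1.18 (FDR 3.46e-07) in the authors' deposited table. The WT libraries themselves differed over this list. CAF1A was at 25.7 RPKM in the deeper and 8.40 in the shallower WT library, and ZAT10 at 13.7 and 5.74. Without the deeper WT library the log2 ratios of RPKM means were -1.01 for CAF1A, -0.58 for ERF104 and -1.02 for ZAT10. For all 17 members with known WT libraries, both of these lay above the jmj28 mean, the lower by a median log2 ratio of 0.39. WT libraries are known here only for members whose WT mean lay above jmj28, since the lowest genotype has no recovered reads. The member above WT in jmj28 is thus not among them.

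Defence and hormone lists moved the same way in jmj28. Of 21 salicylic acid genes, 19 lay below WT and 2 were called, PR1 and the transcription factor gene WRKY70 (log2 fold change -0.88, FDR 0.00226 in the authors' deposited table). Adjusted over the list alone, 5 were lower and 1 higher, and the set test gave an adjusted p of 1.67e-06. Of 22 jasmonate and wounding genes 4 were called and 7 were called when adjusted over the list alone, all lower (adjusted p = 5.93e-11, limma). VSP1 and VSP2, vegetative storage protein genes used as jasmonate markers, had log2 fold changes of -1.21 (FDR listed as 0) and -0.71 (FDR 0.0036) in the authors' deposited table. The abscisic acid, dehydration and cold list had 1 call of 21, RD22 at -0.50 (FDR 0.0124) in the authors' deposited table, 8 calls adjusted over the list alone, and an adjusted p of 5.07e-06. In the senescence and sugar starvation list 3 of 16 were called and 4 adjusted over the list alone (adjusted p = 3.57e-06, limma), among them SAG13 at -1.70 (FDR 0.00169) and DIN6, an asparagine synthetase gene, at -1.21 (FDR 0.000254) in the authors' deposited table.

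Large decreases in jmj28 were also seen in HO3, a heme oxygenase gene, with a log2 fold change of -3.78 (FDR 3.66e-05), the receptor-like kinase gene RFK1 with -3.18 (FDR listed as 0), ASK4, a SKP1-like gene, with -2.46 (FDR listed as 0), and the chitinase family gene AT2G43620 with -2.59 (FDR 5.12e-06) in the authors' deposited table. ASK4 and RFK1 stood at similar levels in the other genotypes, with 6.37 and 6.07 RPKM for ASK4 in the WT libraries and 5.97 and 6.75 RPKM in the JMJ28np5-OE libraries. ERF018 and PUMP4 were lower in jmj28 and higher in JMJ28np5-OE. PUMP4, a mitochondrial carrier gene, was at 14.8 and 3.52 RPKM in the WT libraries. Without the deeper WT library the log2 ratios in jmj28 were -0.87 for PUMP4 and -1.16 for ERF018, and without the shallower it was -1.70 for AT2G43620.

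The tests of this comparison were the authors' own, at the FDR they deposited. Of the 258 lower calls, both WT libraries lay above the jmj28 mean for 253 of the 254 whose WT reads were recovered, and of the 49 higher calls both jmj28 libraries lay above the WT mean for 47 of 48. Since the calls were made on the same libraries, such agreement follows largely from the selection and is no separate support. Requiring both libraries of the higher genotype to be at least 1.5-fold above the other mean left 158 lower and 21 higher genes.

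JMJ28np5-OE against WT had its lowest set-test p in the same stress list, in the other direction. TCH4, a touch-induced xyloglucan endotransglucosylase gene, had a log2 fold change of 1.72 (FDR listed as 0), ZAT10 1.89 (FDR 6.17e-09) and WRKY40 2.14 (FDR 2.01e-07) in the authors' deposited table. The log2 ratio of ZAT10 was 2.63 without the deeper WT library, and that of WRKY40 was 1.24 without the shallower JMJ28np5-OE library. Higher floral and flowering genes were SEP3 at 1.30 (FDR 1.4e-07), AP1 at 1.54 (FDR 0.0213) and SOC1 at 0.49 (FDR 0.000202) in the authors' deposited table. AP1 and SOC1 were 2 of 11 flowering promoters called, and that list's adjusted p of 0.0227 became an adjusted p of 0.0644 with an inter-gene correlation of 0.05. In all, 675 genes were higher and 161 lower at FDR under 0.05 in the authors' deposited table, and 151 and 23 of them changed at least 2-fold.

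**Figure D1:**
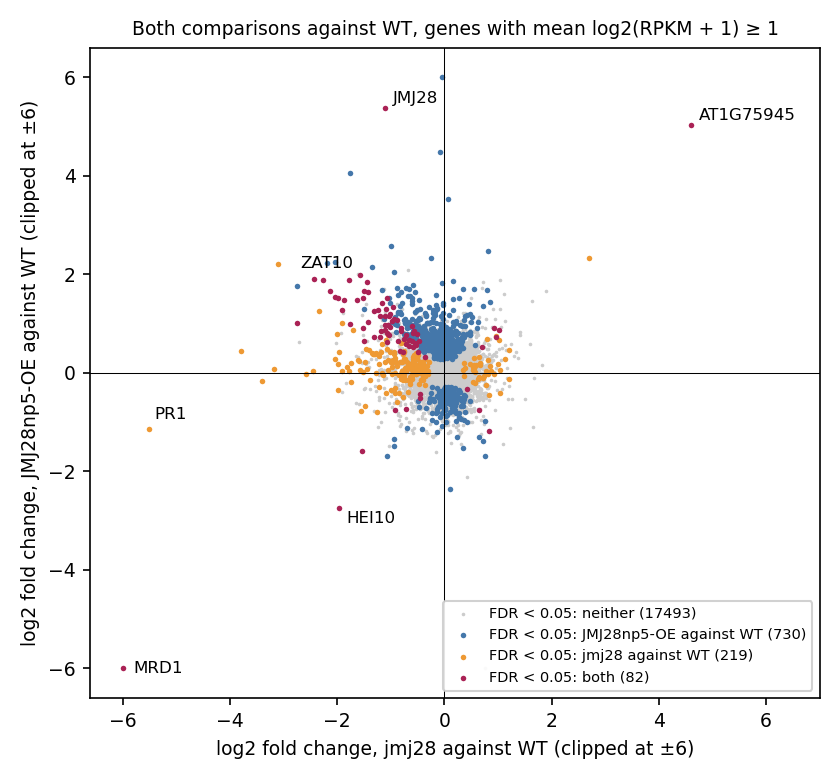
Each point is a gene of at least moderate level (18524 genes), with the log2 fold change of jmj28 against WT on the horizontal axis and of JMJ28np5-OE against WT on the vertical axis, both clipped at 6 in either direction and both from the authors' deposited tables. Colours mark FDR under 0.05 in neither, 1 or both comparisons, and most of the 82 genes called in both lie at the upper left, lower in jmj28 and higher in JMJ28np5-OE.

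All 18 touch and early stress genes lay above WT in JMJ28np5-OE, with a median log2 fold change of 1.34. Of these 15 were called, 17 adjusted over the list alone, and the adjusted p was 1.63e-35 with cameraPR. The libraries within a genotype differed over this list more than over other genes. In JMJ28np5-OE the median size of the log2 ratio between the libraries was 0.64 for the 18 members, against 0.14 for lists of equal expression, and 16 of the 18 were higher in the shallower library. In WT the value was 0.55 against 0.11 over 17 members, and 13 of them were higher in the deeper library. Even so, both JMJ28np5-OE libraries lay above both WT libraries for 16 of the 17 members with all 4 values. Over these 17 the lower JMJ28np5-OE library lay above the higher WT library by a median log2 ratio of 0.49. That is smaller than the list median of 1.34. WRKY40 was at 7.32 and 19.4 RPKM in JMJ28np5-OE against 2.91 and 3.27 RPKM in WT.

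**Figure D2:**
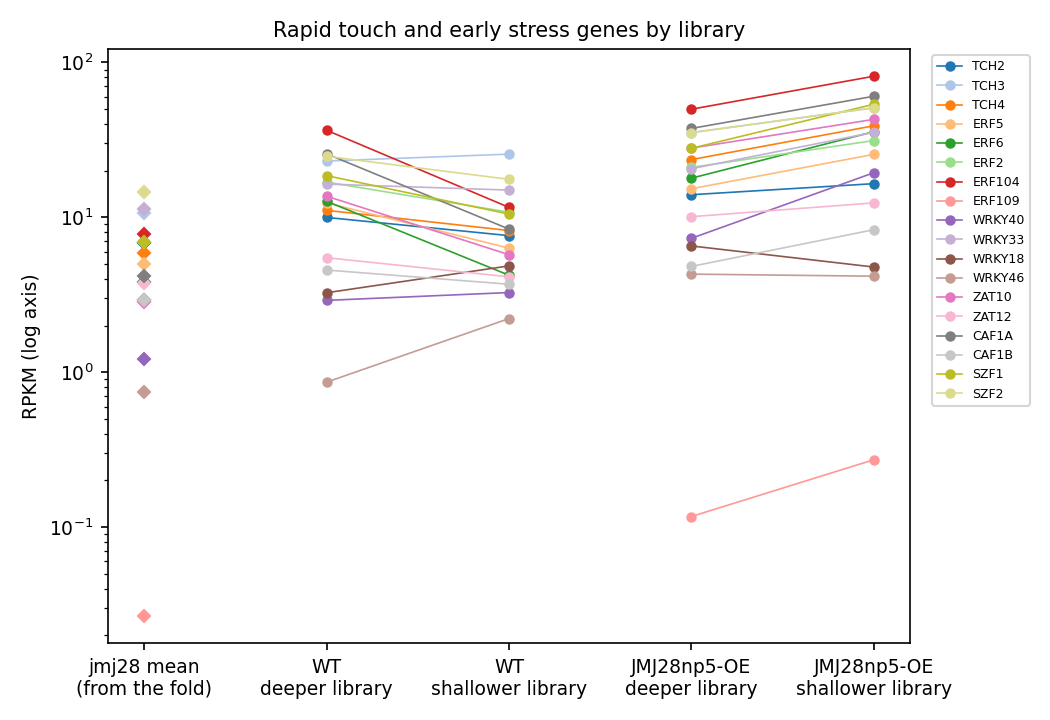
RPKM on a log axis of the 18 rapid touch and early stress genes in the recovered WT and JMJ28np5-OE libraries, with lines joining the libraries of a genotype, and the jmj28 mean from the authors' fold change as diamonds. Of the lines, 13 of 17 fall from the deeper to the shallower WT library and 16 of 18 rise from the deeper to the shallower JMJ28np5-OE library, and ZAT10 runs from 13.7 and 5.74 in WT to 28.0 and 42.9 in JMJ28np5-OE.

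Salicylic acid genes were higher in JMJ28np5-OE, with 20 of 21 above WT, 5 called and 13 higher and 1 lower when adjusted over the list alone (adjusted p = 1.76e-09, limma). SARD1, a regulator of salicylic acid synthesis, had a log2 fold change of 1.24 (FDR 0.000872), WRKY70 1.07 (FDR 1.06e-05) and PR2, a glucanase gene, 2.23 (FDR 0.0204) in the authors' deposited table. The PR genes varied strongly between libraries. PR2 was at 38.6 and 11.1 RPKM in JMJ28np5-OE and at 1.1 and 9.65 in WT, and PR1 was at 10.3 and 2.19 RPKM in JMJ28np5-OE and at 14.7 and 13.2 in WT. The log2 ratio of PR2 was 1.04 without the deeper JMJ28np5-OE library and 1.36 without the deeper and 4.50 without the shallower WT library. Of 22 jasmonate genes 14 lay above WT and 8 below. Of the 22, 5 were called, all higher, with 7 higher and 1 lower adjusted over the list alone (adjusted p = 8.97e-06, limma, and 0.0328 on ranks). MYC2, a central transcription factor of jasmonate signalling, had 1.87 (FDR 4.84e-10), JAZ1 0.84 (FDR 9.4e-06) and VSP1 1.16 (FDR listed as 0) in the authors' deposited table.

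Clock lists rose modestly. Of 11 evening-phased genes 10 lay above WT, 3 were called and 7 when adjusted over the list alone (adjusted p = 8.97e-06, limma), namely COR28 at 0.70 (FDR 8.23e-05), BOA at 0.67 (FDR 0.000421) and PRR3 at 0.37 (FDR 0.00512) in the authors' deposited table. All 9 morning-phased genes lay above WT with 2 called, PRR7 at 0.64 (FDR 0.000157) and LNK2 at 0.85 (FDR 0.000806) in the authors' deposited table, the same 2 as a count adjusted over the list alone, and an adjusted p of 0.00351. Senescence genes gave 2 higher and 1 lower call of 16, with 6 higher and 1 lower adjusted over the list alone (adjusted p = 8.09e-05, limma). The senescence regulator gene NAP had 1.70 (FDR 0.00176) and SEN1 1.28 (FDR 3.41e-06), while the dark-inducible gene DIN11 had -1.68 (FDR 0.0224) in the authors' deposited table. DIN11 was at 5.65 and 1.54 RPKM in WT, and its log2 ratio was -0.46 without the deeper WT library. Cell cycle genes ran below WT in all 17 members, with a median of -0.25, 1 call, RNR1 at -0.37 (FDR 0.00511) in the authors' deposited table, 4 calls adjusted over the list alone, and an adjusted p of 8.97e-06.

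**Figure D3:**
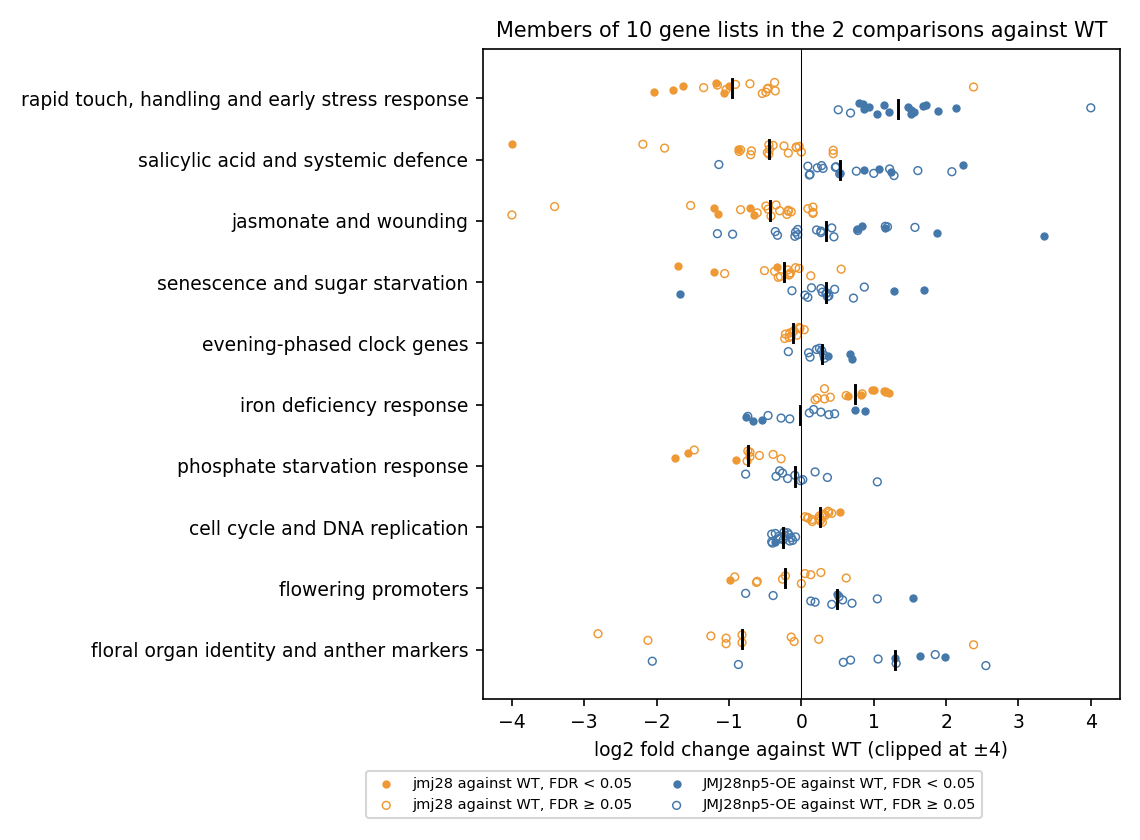
Log2 fold changes against WT of the members of 10 gene lists, clipped at 4 in either direction, from the authors' deposited tables, with jmj28 in orange and JMJ28np5-OE in blue. Filled points passed FDR 0.05, open points did not, and each black bar is the list's median, which for the touch and early stress list is -0.96 in jmj28 and 1.34 in JMJ28np5-OE.

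Iron genes split in JMJ28np5-OE. IRT1 at 0.74 (FDR 0.0306) and FRO2 at 0.88 (FDR 0.0263) were higher, whereas IMA3 at -0.76 (FDR 0.000111), the phloem transporter gene OPT3 at -0.67 (FDR 2.99e-05) and NAS4, a nicotianamine synthase gene, at -0.54 (FDR 0.0346) were lower in the authors' deposited table. Adjusted over the list alone 2 were higher and 4 lower, and the list as a whole did not pass the set test (adjusted p = 0.0761, limma). Photosynthesis genes had 2 calls of 23, LHCB3 at 0.53 (FDR 0.00136) and LHB1B1 at 0.40 (FDR 0.0459) in the authors' deposited table, with 3 adjusted over the list alone and an adjusted p of 0.0227 that became 0.114 with an inter-gene correlation of 0.05. In the abscisic acid list only NCED3 was called, at 1.00 (FDR 0.0408) in the authors' deposited table. Its JMJ28np5-OE libraries were at 2.19 and 4.62 RPKM, and its log2 ratio was 0.30 without the shallower. That list had 2 higher and 1 lower adjusted over the list alone, and an adjusted p of 0.132.

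Outside the lists, large increases in JMJ28np5-OE were seen in BAM5, a beta-amylase gene, with a log2 fold change of 2.57 (FDR 1.73e-08), ERF13 with 2.25 (FDR 0.000695), BAP2 with 2.48 (FDR 0.0143) and the pollen allergen family gene AT5G22430 with 4.49 (FDR 1.14e-12) in the authors' deposited table. BAP2 was at 4.26 RPKM in the deeper and 1.27 in the shallower JMJ28np5-OE library. The log2 ratios were 1.30 for BAP2 and 1.98 for BAM5 without the deeper JMJ28np5-OE library, and 1.52 for ERF13 without the shallower WT library. ERF105 (chromosome 5, 20800473 to 20801437) had 117 and 368 reads in JMJ28np5-OE and 0 reads in all libraries of WT and jmj28. This gene lies wholly inside the model of AT5G51180 on the other strand, and the library kit does not mark strand. No fold is given, since a group at 0 reads has none. Lower genes included the jacalin lectin gene JAL41 with -1.34 (FDR 0.000903), the lectin kinase gene LECRK15 with -1.31 (FDR 0.012) and the ferric reductase gene ATFRO5 with -1.20 (FDR 0.00786) in the authors' deposited table.

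For the higher calls of this comparison, both JMJ28np5-OE libraries lay above the WT mean in all 663 genes whose reads were recovered, and all 4 libraries were apart in 402 of the 403 genes with both genotypes known. These genes were called on the same libraries, so such agreement follows largely from the selection and is no separate support. At least 1.5-fold changes at FDR under 0.05 numbered 407 higher and 73 lower.

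Flowering genes were examined by name, because CO and FT are the photoperiod genes of this pathway. SOC1 (chromosome 2, 18807505 to 18811125), an integrator of flowering signals, was at 29.3 and 31.4 RPKM in the JMJ28np5-OE libraries and 22.4 and 24.1 RPKM in the jmj28 libraries. The log2 fold change of SOC1 in jmj28 against WT was 0.05 (FDR 1) in the authors' deposited table. SPL3, a promoter of the floral transition, was lower in jmj28 at -0.98 (FDR 0.000423) in the authors' deposited table. Of 11 flowering promoters tested without CO and FT, 1 was lower in jmj28 (1 adjusted over the list alone, adjusted p = 0.101 with limma). In JMJ28np5-OE 2 were higher (2 adjusted over the list alone), with an adjusted p of 0.0227 that became 0.0644 with an inter-gene correlation of 0.05. FLC, the vernalization-regulated repressor, was at 1.12 and 0.829 RPKM in WT, and its log2 fold change of -1.90 in JMJ28np5-OE did not pass (FDR 0.138 in the authors' deposited table). The repressor genes TEM1 and TEM2 were lower in jmj28 at -1.08 (FDR 4.97e-07) and -1.04 (FDR 7.12e-05), and higher in JMJ28np5-OE at 0.62 (FDR 0.0129) and 0.78 (FDR 0.00387) in the authors' deposited tables. The 19 repressors as a list had 2 calls in each comparison against WT and did not pass the set test (adjusted p = 0.309 in jmj28 and 0.28 in JMJ28np5-OE, limma). Adjusted over the list alone 2 were lower in jmj28, and 3 were higher and 1 lower in JMJ28np5-OE. Floral organ genes rose in JMJ28np5-OE, with SEP1, SEP2 and SEP3 called, 4 adjusted over the list alone, of 11 tested (adjusted p = 8.09e-05, limma). SEP3 was at 10.5 and 10.3 RPKM there, against 4.39 and 4.18 RPKM in WT. The log2 ratio of SEP2 was 1.35 without the shallower and 3.40 without the deeper WT library. Like the root list, the floral organ list was fixed as a marker of other tissue that the harvest could hold. Whether the JMJ28np5-OE samples held a larger share of floral tissue was not tested, and it cannot be told apart here from a change of these genes.

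The entries for CO (AT5G15840, chromosome 5, 5170162 to 5173085) and FT (AT1G65480, chromosome 1, 24331373 to 24333999) could not be used. For every other tested gene the log2 fold changes of the 3 comparisons add up within 0.001, as one model for all genotypes gives, whereas those of CO and FT miss by 0.198 and 0.244 in the authors' deposited tables. In jmj28 against WT the fold change, p-value and FDR of CO equal those of CYP76C6 (AT1G33720) in every digit, and those of FT equal those of AT5G44260, with log2 fold changes of -0.66 for both in the authors' deposited table. In JMJ28np5-OE against WT the entries equal those of AT1G63350 and UGT75C1, at 0.64 for CO and 0.61 for FT in the authors' deposited table. In jmj28 against JMJ28np5-OE they equal those of AT3G16070 and NUDT6, at -1.10 and -1.03 in the authors' deposited table. Among the genes of at least 1 RPKM no other pair shares these values in any of the tables. The mean of CO in jmj28 against WT, 1.52 RPKM, also equals that of CYP76C6, so no level of CO in jmj28 or WT is known. Its mean in the other tables, 1.77 RPKM in both, is shared by no such gene and gives 1.74 and 1.80 RPKM in the JMJ28np5-OE libraries (63 and 56 reads). The means of FT differ from those of the genes that share its other values, and give 4.84 and 3.57 RPKM in jmj28 (64 and 41 reads) and 4.56 and 2.70 RPKM in JMJ28np5-OE (55 and 28 reads), with WT lowest. By these means FT was highest in jmj28, whereas its listed log2 fold changes of -0.66 and -1.03 put jmj28 below WT and below JMJ28np5-OE. The deposited FDR of the other genes was set against a Benjamini-Hochberg FDR recalculated from the listed p-values over 34262 genes. With CO and FT as listed, 2178 of 23532 values in jmj28 against WT and 6733 of 23532 in JMJ28np5-OE against WT differed by more than a relative 1e-09, and 0 did once both p-values were moved to the largest. The ranks behind the deposited FDR place the p-values of both genes above 0.07976 in jmj28, where 0.0362 and 0.00342 are listed for CO and FT, and above 0.2486 in JMJ28np5-OE, where 0.0123 and 0.01645 are listed in the authors' deposited tables. In jmj28 against JMJ28np5-OE 10152 of 23463 values differed as listed and 1608 after the move, and the ranks place 1 of the p-values between 0.3482 and 0.3483 and the other above 0.4311, against listed values of 0.0458 and 0.0268. The listed p-values of CO and FT are thus smaller than those behind the deposited FDR of the other genes. No change of CO or FT is therefore reported here.

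jmj28 against JMJ28np5-OE compared the lowest with the highest JMJ28 level directly. ZAT10 had a log2 fold change of -3.67 (FDR listed as 0), PR2 -4.41 (FDR 2.67e-09) and VSP1 -2.37 (FDR listed as 0), while IMA3 had 1.41 (FDR listed as 0) in the authors' deposited table. The log2 ratio of PR2 was -3.23 without the deeper JMJ28np5-OE library. In all, 971 genes were higher and 1716 lower in jmj28 at FDR under 0.05 in the authors' deposited table. Of the 18 touch genes 17 were lower (17 adjusted over the list alone, median -2.24, adjusted p = 5.87e-42, limma). The limit given above on the p of this list holds here as well. Lower calls also numbered 14 of 21 salicylic acid genes (17 lower and 1 higher adjusted over the list alone), 11 of 22 jasmonate genes (12), 9 of 16 senescence genes (9), 7 of 21 abscisic acid and cold genes (10), 5 of 11 evening clock genes (8) and 4 of 11 phosphate genes (6). Of these, CBF1 and CBF2, cold-response factor genes, had -2.83 (FDR 0.00119) and -3.33 (FDR 0.000793) in the authors' deposited table. Without the shallower JMJ28np5-OE library their log2 ratios were -2.13 and -2.72. Higher calls numbered 9 of 17 cell cycle genes (14 adjusted over the list alone), 8 of 14 iron genes (10) and 4 of 14 root markers (5). KN, a cytokinesis syntaxin gene, had 0.83 (FDR 9.81e-07) and SKOR, a root potassium channel gene, 1.13 (FDR 0.00136) in the authors' deposited table. Each of these lists passed the set test, with adjusted p-values from limma of 6.73e-05 or less.

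In the flowering lists AP1 was lower in jmj28 than in JMJ28np5-OE at -2.46 (FDR 0.00013), SPL3 at -1.11 (FDR 5.94e-06), SPL5 at -1.32 (FDR 0.0364) and SOC1 at -0.44 (FDR 0.000687), and AGL24 was higher at 0.53 (FDR 0.0342) in the authors' deposited table. That list had 6 lower and 1 higher adjusted over the list alone and an adjusted p of 0.00519. FLC was higher at 2.05 (FDR 0.0396), and TEM1, TEM2 and SVP were lower in the authors' deposited table. Floral organ genes were lower, with 5 calls of 11 and 5 adjusted over the list alone (adjusted p = 0.000297, limma). The limit given above on the share of floral tissue holds here as well. Smaller groups of calls were 4 lower photosynthesis genes of 23 (5 adjusted over the list alone, adjusted p = 0.000612), 3 lower nitrate genes of 5 (3, adjusted p = 0.0215), 2 lower and 1 higher glucosinolate genes of 14 (7 and 1, adjusted p = 0.0082) and 2 lower morning clock genes of 9 (2, adjusted p = 0.0946). Flavonoid genes split, with F3H, CHS, CHI and FLS1 higher and PAP2 and GSTF12 lower (adjusted p = 0.561, limma). Genes higher in jmj28 included DOF5.8 at 2.76 (FDR 0.00159), GGPPS9 at 2.54 (FDR 2.76e-05) and P4H8 at 2.35 (FDR 0.000784) in the authors' deposited table. TAT3, a tyrosine aminotransferase gene, was lower at -5.31 (FDR 3.21e-08) in the authors' deposited table, with 0.212 and 9.15 RPKM in the WT libraries. Its log2 ratio was -4.08 without the deeper JMJ28np5-OE library. At least 1.5-fold changes numbered 446 higher and 1051 lower.

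The lists without a call in either comparison against WT were the FBH transcription factors (4 tested, 1 member with an unadjusted p under 0.05 in jmj28 and 0 in JMJ28np5-OE), heat shock genes (15, 0 and 3), sulfur starvation genes (9, 3 and 3), aliphatic glucosinolate genes (14, 2 and 3), auxin response genes (14, 2 and 2), loci silenced by DNA and H3K9 methylation (5, 0 and 0) and seed storage markers (4, 0 and 0), all by the authors' test. Adjusted over the list alone, the sulfur list had 2 lower genes in each comparison, the auxin list 1 lower in jmj28 and the glucosinolate list 1 higher in JMJ28np5-OE, and the other lists named here had 0. The set test gave adjusted p-values in jmj28 and JMJ28np5-OE of 0.607 and 0.591 for the FBH genes, 0.607 and 0.553 for heat shock, 0.133 and 0.111 for sulfur, 0.796 and 0.606 for the silenced loci, and 0.219 and 0.532 for the seed markers. The glucosinolate and auxin lists passed the set test in jmj28 with adjusted p-values of 0.0228 and 0.0449, which became 0.076 and 0.109 with an inter-gene correlation of 0.05. The same held for the evening clock genes (0.0477, then 0.109) and photosynthesis genes (0.0227, then 0.0987), all with small decreases in jmj28. The evening clock and photosynthesis lists had 0 calls in jmj28, with 0 and 2 members at an unadjusted p under 0.05 in the authors' test. The morning clock and floral organ lists also had 0 calls there, each with 0 such members (adjusted p = 0.428 and 0.113, limma). Organelle-encoded genes, a sign of RNA selection, had 0 and 2 calls of 141 tested, both lower, with 4 and 10 members at an unadjusted p under 0.05, 0 and 1 adjusted over the list alone, and adjusted p-values of 0.656 and 0.776 for the list. Phosphate and root lists had 0 calls in JMJ28np5-OE, with 0 and 1 members at an unadjusted p under 0.05, and the flavonoid and nitrate lists had 0 calls there with 4 and 1 such members. Adjusted p-values in JMJ28np5-OE were 0.545 for phosphate, 0.0556 for root markers, 0.534 for flavonoid and 0.277 for nitrate genes, and the JMJ28 family passed (0.0227) through JMJ28 itself, with 0.456 on ranks. On ranks the root markers in JMJ28np5-OE passed with an adjusted p of 0.0249, with 11 of 14 below WT.

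A few lists had a median, mean and test that differ in sign. In jmj28 against WT the flavonoid list had a median log2 fold change of 0.24 and a mean of -0.27 with an upward test, the flowering repressors 0.13 and -0.03 with a downward test, the JMJ28 family 0.02 and -0.13, and the silenced loci -0.12 and 0.36, the last 2 with a downward test. In JMJ28np5-OE against WT the auxin list had -0.05 and 0.02 with an upward test, and the organelle list 0.02 and 0.04 with a downward test. In jmj28 against JMJ28np5-OE the repressors had 0.02 and -0.09 with a downward test, the sulfur list 0.09 and -0.01 with an upward test, and the flavonoid list -0.39 and -0.55 and the organelle list -0.05 and -0.28 with upward tests. None of these lists passed the set test in these comparisons.

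The largest overlap of the comparisons against WT was between genes lower in jmj28 and genes higher in JMJ28np5-OE. Of the 258 genes lower in jmj28, 67 were higher in JMJ28np5-OE, against 7.4 for independent lists of these sizes. JMJ28 itself is 1 of the 67, and 6 are touch list members, namely CAF1A, ZAT10, ERF104, TCH3, SZF1 and ERF2. Genes higher in both numbered 5 (1.41 for independent lists), among them IRT1, FRO2 and AT1G75945. Lower in both were 7 (1.76), with MRD1, HEI10 and AT4G20362 among them, and 3 were higher in jmj28 and lower in JMJ28np5-OE (0.335), including IMA3. AT1G75945 (chromosome 1, 28515245 to 28515916), which codes for an uncharacterized protein, had 94 and 98 reads in jmj28 and 109 and 117 in JMJ28np5-OE, and its log2 fold change against WT was 4.60 and 5.04 in the authors' deposited tables. MRD1 (chromosome 1, 19963047 to 19964712) had 629 and 536 reads in WT and 2 and 0 in JMJ28np5-OE. HEI10, a gene of meiotic crossover formation that overlaps MRD1 on the other strand (19963267 to 19966952), had log2 fold changes of -1.97 and -2.76 in the authors' deposited tables. In total 195 of the 258 genes lower in jmj28 had a fold change above 0 in JMJ28np5-OE, and 450 of the 675 genes higher in JMJ28np5-OE had one below 0 in jmj28. The 49 genes higher in jmj28 were not reciprocal, since 32 of them also lay above 0 in JMJ28np5-OE, with a median log2 fold change of 0.10 in the authors' deposited table. Of the 161 genes lower in JMJ28np5-OE, 105 lay above 0 in jmj28. Unchanged genotypes simulated against the same WT libraries shared 0 calls in each of 100 draws, but made a mean of 0.1 calls per comparison, so these draws say nothing about the shared counts. Across 18501 genes of at least moderate level and known exon length the log2 fold changes had a correlation of -0.01 where the simulation gave 0.40, and a covariance of -0.001 where the simulation gave 0.013. Genes are not independent replicates. The WT libraries could not be split, so part of the overlap in the same direction can come from sharing them. The same holds for the 32 of the 49 genes above 0 in both comparisons.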

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

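All tests in this part were chosen only after the result they address was seen, except the comparison of the JMJ28np5-OE libraries over the touch list. No group held enough samples for a search for samples apart from the rest.

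The rapid touch and early stress genes ran jmj28 below WT below JMJ28np5-OE, with list medians of -0.96 and 1.34 against WT. A scaling offset left in the deposited fold changes is argued against, since the median log2 fold change of all tested genes was at most 0.004 in size. Normalization can itself centre this median, so it cannot show whether all genes shifted before that step. Unequal handling of seedling pools at harvest may contribute and stays open. The list's median size of the log2 ratio between the JMJ28np5-OE libraries lay at percentile 100 among 10000 lists matched for expression. These lists were drawn gene by gene, whereas touch genes can move together. The percentile thus shows that the list differed between libraries of the same genotype, but does not point to handling in particular. The level of JMJ28 itself stays open as well, with 17 of 18 members in that order, and cannot be told apart from handling because nothing in the design separates genotype from harvest. The 67 genes lower in jmj28 and higher in JMJ28np5-OE include 6 of these genes, so the same doubt extends at least to those 6. Of the other genes among the 67, ERF018 and PUMP4 also depended on the deeper WT library. Without it their log2 ratios in jmj28 were -1.16 and -0.87, against deposited log2 fold changes of -2.43 and -2.25. FAMT depended on the shallower WT library, with -1.02 without it against -2.13. Differences between libraries thus reach beyond the 6. Over the rest of the 67 as a set the libraries were not compared, so how far the doubt reaches is not known.

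MRD1, HEI10 and AT1G75945 differed from WT the same way in both lines. A fall of MRD1 made only of reads moved to the overlapping model of HEI10 is argued against, since HEI10 fell too, with a highest log2 fold change of -1.97. The models share 1446 bases and the library kit does not mark strand. A fall of MRD1 alone could therefore lower the count of HEI10 as well, which was not tested, so HEI10 may not be a separate change. The level of JMJ28 moves in opposite directions in these lines. All 3 genes were picked because they were called the same way in both. That they do not follow this level in a single direction is thus given by how they were picked, and is not a test. A like response to both a lower and a higher level was not tested and stays open. A sequence difference between the WT plants and the other lines at these loci could account for it and stays open, with 1 called gene (FAP3) among 10 expressed genes within 10 kb, since expression alone does not show sequence.

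Of the expressed genes 7 had reads in 1 genotype and none, or under 0.5 read by the fold, in another, and 6 of them overlap another tested gene against 4771 of 17390 others (odds ratio 15.9, two-sided Fisher's exact test, p = 0.00229). A fall of MRD1 made only of reads moved to HEI10 is argued against, since HEI10 fell with it. Reads moved between overlapping models are also argued against for THI2.1, which shares only 24 bases with AT1G72250, fewer than the 150 of a read. Of the other 5, only ERF105 was called, and 4 of the 5 overlap another tested gene (odds ratio 10.6, two-sided Fisher's exact test, p = 0.0221). For those 4, reads given to 1 model or the other may account for the genotypes at 0, and this stays open. A rise of ERF105 made only of reads taken from AT5G51180 is argued against, since AT5G51180 rose too (log2 fold change 0.85 in the authors' deposited table), but this says nothing about the 0 reads of ERF105 in WT and jmj28. ERF105 lies wholly inside that model and the kit does not mark strand. Reads of ERF105 could therefore raise the count of AT5G51180, which was not tested, so AT5G51180 may not be a separate change. RPL30A, with 34 reads in 1 jmj28 library, overlaps no other tested gene, so reads shared between overlapping models do not account for it. No biological explanation was tested for this set.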

How the results depend on the processing

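The Bonferroni, both-library, overlapping-model, organelle, tested-gene FDR, correlation, rank, RPKM-ratio and left-out-library alternatives were chosen only after the data were seen. Thresholds and the 1 RPKM minimum were planned. No paired analysis was possible because the means carry no replicate number. Count-model fits, other normalizations, count filters, the replicate block, leaving out each library in the tests, the pseudocount, the variance model, the estimated correlation and fry were not run, since they need a value per library for every genotype. Directions of calls cannot turn under a change of threshold.

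Unadjusted p under 0.05 with at least 1.5-fold gave 255 higher and 531 lower genes in jmj28 against WT and 317 lower in JMJ28np5-OE against WT, and overlaps of 33 (both higher), 14 (higher in jmj28, lower in JMJ28np5-OE), 146 (the other way) and 26 (both lower). FDR under 0.05 with at least 1.5-fold gave 407 and 73 in JMJ28np5-OE against WT and 446 and 1051 in jmj28 against JMJ28np5-OE. A minimum of 1 RPKM gave 243 lower genes in JMJ28np5-OE against WT, where fewer genes were adjusted for. Bonferroni gave 9 and 86, 189 and 21, and 101 and 529 higher and lower genes in the 3 comparisons. Both libraries of the higher genotype at least 1.5-fold above the other mean gave 21 and 158, 230 and 54, and 367 and 748, counting genes without recovered libraries as failing. Without overlapping gene models 1 gene was higher in jmj28 and lower in JMJ28np5-OE, and 4 were lower in both. An inter-gene correlation of 0.05 left 9 lists past the set test in jmj28 against WT. These changes follow from stricter or looser criteria or from fewer genes. The other counts for whole comparisons stayed within 1.5 times the values reported. Of the counts of calls within single lists, 27 went up and 11 down by more than that with unadjusted p and 1.5-fold, 13 went down with FDR and 1.5-fold, and 2 went up with FDR over the tested genes. Of 199 log2 fold changes of named genes, 196 differed from the ratio of RPKM means by less than the replicate SD of 0.27, 3 moved and 0 reversed, the largest difference being 0.55. Leaving out 1 recovered library moved 40 of 229 called values of named genes by more than 1.5-fold. TAT3 in jmj28 against WT had -3.10 (FDR 0.0282) in the authors' deposited table, and log2 ratios of 1.36, a reversal, without the shallower WT library and -4.07 without the deeper. On ranks the nitrate list in jmj28 and the JMJ28 family in JMJ28np5-OE no longer passed, and the root markers in JMJ28np5-OE passed.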

Other observations

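The 67 genes lower in jmj28 and higher in JMJ28np5-OE held a cluster of TIR-domain genes on chromosome 1, found on looking through the calls and not tested as a group. AT1G72900, AT1G72910, AT1G72920 and TIR (AT1G72930) had log2 fold changes of -0.97, -1.52, -1.57 and -0.77 in jmj28 and 1.06, 1.52, 1.98 and 0.43 in JMJ28np5-OE in the authors' deposited tables. The receptor kinase gene SOBIR1, which acts in defence signalling, had -0.54 and 0.61, and the kinase gene MKK9 had -0.94 and 1.09 in the authors' deposited tables.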
